A study of Mus musculus with 6 samples.

How the data were processed

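Total RNA was extracted with TRIzol from primary CD8+ T cells of mouse spleen, and libraries were made with a whole-RNA or an mRNA kit, per the labels' protocols. Which kit each library had, and how the cells were isolated, is not given in the sources used here. The reads were processed against mm10, per the submitters' processing notes. The aligner, the counter, its strand setting and the annotation are not given in the sources used here, so antisense and overlapping genes cannot be told apart from their partners.

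The deposited table, a signal that the authors obtained by scaling read counts, holds normalized counts of 19323 Ensembl genes in 6 libraries, per the file headers. In 5 of the 6 libraries 100% of the values came out as whole reads, at a tolerance of 0.01, when divided by the smallest value above 0. ND replicate 3, whose smallest value above 0 lay near 1, was left out of the count tests as a precaution against rounded values. The recovered totals were 13188812 to 15482458 reads. Symbols were matched by gene identifier for 19202 genes, and coordinates by identifier to GENCODE M21 on mm10. The authors' annotation may be another one.

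Libraries were grouped by the diet in their labels, 3 ND and 3 MCDHFD. Genes with a mean of at least 10 over the 6 libraries were tested, 13430 in all, on log2 of the value plus a pseudocount of 1. Fold changes are on that scale, which understates the change of low genes. The main test was limma 3.58.1 with an intensity trend and diet as the only term, in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The deposited scaling was kept, and a limma test on logs was the main test because the values are scaled. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 50 of 53 lists with at least 5 tested genes. The lists and tests were fixed before the data were examined. The gene sets were written from general knowledge, and some genes stand in more than 1 list. The two-sided exact permutation test of Trnp1 used all 20 arrangements.

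Named genes followed a fixed rule: Trnp1, Cd3e, Cd8a, Cd8b1 and Cd4, the 10 highest and 10 lowest fold changes among genes past the threshold with a mean of at least 50 and non-overlapping diets, passing over symbols of the Gm or Rik kind, up to 4 passing members per functional list by size of change, and up to 3 members of the highest mean per other list. Of the 212 genes that the rule names, 121 are in the text, and 2 are withheld and not reported here. Examples were taken in that order, and how many each list got, down to none, was decided after their values and their stability were seen. The genes in the text are therefore more stable than those the rule names, and the counts over all of the latter are given with the alternatives. The 4 pairs of libraries of the same diet with recovered reads had chi-square values per degree of freedom of 6.46 to 12.3, so none of these pairs agreed within sampling noise. The pairs with ND replicate 3 were compared by correlation only.

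Alternatives were other pseudocounts and filters, TMM and quantile scaling, library quality weights, the replicate number as a block, leaving out each library, stricter thresholds, other list tests, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads of 5 libraries (2 ND, 3 MCDHFD). A scaling to equal CD8 T cell identity, the omission of genes of other cell lists and functional lists without such genes were added after seeing the data. The procedure was tested on simulated counts for the comparison of MCDHFD with ND, on 13430 genes of which 200 were changed singly and others as a list. It called 66.0% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and 14 of 13200 unchanged genes. These 14 were 6.48% of its calls. The simulation changed far fewer genes than passed in the data and used the same dispersion, 0.0106, for all genes. It therefore does not measure the error in the data. Floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules.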

Results

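RNA was sequenced from CD8+ T cells of the spleens of C57BL/6 mice that were 6 weeks old when they were given either of 2 diets for 7 weeks. The labels call the diets ND and MCDHFD and name the fed animals as models of MASH, a fatty liver disease with inflammation. There were 3 libraries per diet. The deposited normalized counts summed to between 14119816 and 14752121 per library, and the 5 libraries whose whole reads were recovered held between 13188812 and 15482458 reads. Correlations of log2 values between libraries of the same diet ran from 0.985 to 0.988, and those between diets from 0.896 to 0.916. The labels do not say that the replicates came from separate animals, so p-values measure only the spread between these samples, which can be technical.

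The comparison of the diets asks how the splenic CD8+ T cell transcriptome differed after MCDHFD, with Trnp1, the gene named in the title of the series, as its main item. Trnp1 encodes a nuclear protein studied for its part in cell proliferation and brain development. It rose from 177 ± 25.9 to 2339 ± 72.4 normalized counts (mean ± SD, n = 3 per diet), a log2 fold change of 3.73 (SE 0.11, limma adjusted p = 7.25e-08). Trnp1 was higher in each of the 3 MCDHFD libraries than in each ND library. The T cell co-receptor genes moved the other way. Cd8a fell from 13784 ± 350.4 to 5264 ± 458 normalized counts (log2 fold change -1.39, SE 0.07, limma adjusted p = 5.41e-07) and Cd8b1 from 10766 ± 332 to 4458 ± 352 (log2 fold change -1.27). Cd3e, a signalling chain of the T cell receptor complex, fell from 3670.4 ± 177 to 1840.3 ± 140.1 (log2 fold change -0.997). Cd4, the co-receptor of helper T cells, was measured at 289.7 ± 32.4 to 331 ± 48.3 from ND to MCDHFD and did not pass the test (limma adjusted p = 0.258).

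In mm10 coordinates, these genes lie as follows. Trnp1 (ENSMUSG00000056596, chromosome 4, 133491100 to 133498550, minus strand) is protein-coding, with 2 annotated transcripts of up to 3 exons. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173) and Cd8b1 (ENSMUSG00000053044, chromosome 6, 71322788 to 71337494) are protein-coding genes on the plus strand. An exact two-sided permutation test of Trnp1 gave p = 0.1, the smallest p that 3 against 3 libraries allow. By log2 fold change Trnp1 ranked 149 among the tested genes, and by p it ranked 21.

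**Figure D1:**
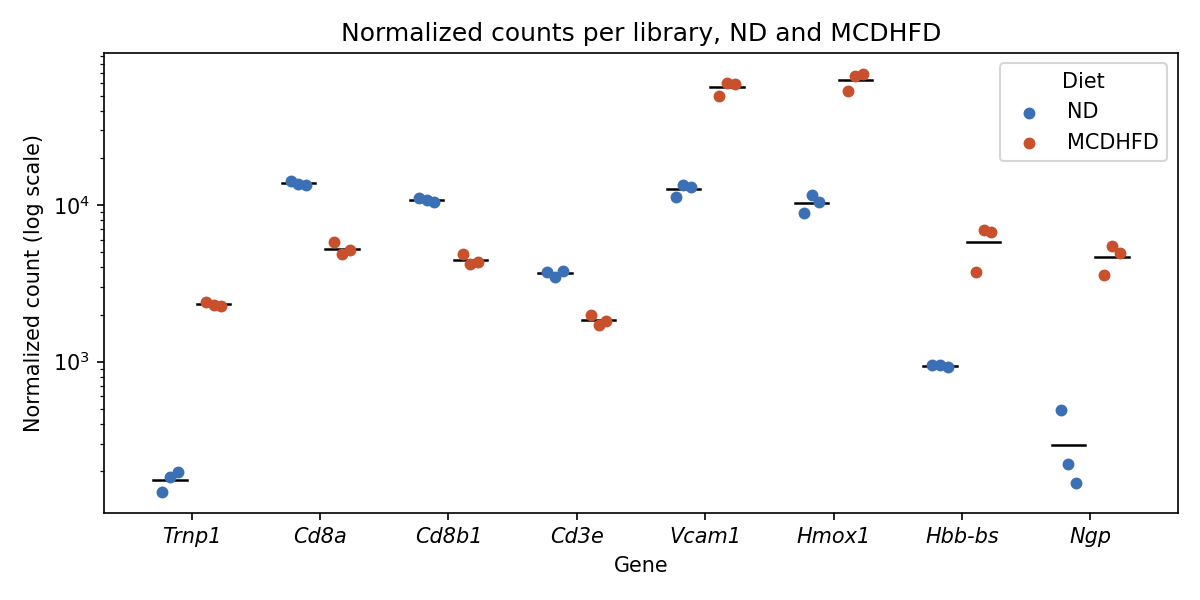
Normalized counts (log scale) of 8 genes in the 3 ND libraries (blue points) and the 3 MCDHFD libraries (orange points), with the mean of each diet as a black line. Trnp1 rose from a mean of 177 to 2339, while Cd8a fell from 13784 to 5264 and Vcam1 rose from 12596 to 56721.

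Across the transcriptome, 7837 of 13430 tested genes (58.4%) differed between the diets in limma at an adjusted p under 0.05, with 4065 higher and 3772 lower in MCDHFD. Of these, 1756 were higher and 1029 lower by at least 2-fold. The groups did not overlap in 8789 tested genes (65.4%), where chance gives 10%. The first principal component, which separated the diets, held 83.4% of the variance. With the mean log2 value of the CD8 T cell identity list held equal in all libraries, a scaling added after seeing the data, the split became 11056 higher and 488 lower. That scaling moved the median log2 fold change of all tested genes by 0.99, so gene groups below are described relative to the tested genes as a whole. Under it Cd4 passed (log2 fold change 1.18, limma adjusted p = 7.15e-05), near that shift. Under quantile scaling the split turned to 3552 higher and 4557 lower.

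Among genes with a mean of at least 50, the highest fold changes included genes of neutrophil granules, of the stefin family and of pancreatic proteases. Of the neutrophil granule genes, Elane rose from 1.63 ± 1.13 to 338 ± 114 normalized counts, Ctsg from 0.326 ± 0.565 to 187 ± 80.7 and Mpo from 7.82 ± 8.01 to 757 ± 286. The log2 fold change of Mpo, 6.85, was 7.60 without ND replicate 1 and 6.03 without ND replicate 3. Msr1, a macrophage scavenger receptor, rose from 19.6 ± 2.08 to 2569 ± 279.6. Mt2, a metallothionein, rose from 2.94 ± 1.70 to 369.9 ± 29.3, and Car1, a carbonic anhydrase of red cells, from 19.3 ± 5.31 to 1824 ± 379. Ctrb1, a pancreatic chymotrypsinogen, was at 0 in all ND libraries and at least 68.1-fold higher in MCDHFD, against a floor of 3 counts per library. The stefin gene Stfa2 was likewise at 0 in ND and at least 44.4-fold higher. Stfa1 (from 0.651 ± 0.563 to 130.4 ± 42.3) and the trypsin gene Try5 (from 0.326 ± 0.565 to 151 ± 45.4) belong to families of similar copies, so their values are uncertain. The ND means of Elane, Ctsg, Stfa1 and Try5 lay below that floor, so no fold is given for them.

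The genes with the lowest fold changes included several tied to antigen-presenting and B cells. Il12b, a subunit of interleukin-12, fell from 152 ± 29.6 to 10.3 ± 8.28 normalized counts, and Fscn1, an actin-bundling protein of mature dendritic cells, from 567 ± 139 to 35.9 ± 7.68. Fcer2a, the low-affinity IgE receptor of B cells, fell from 423 ± 33.7 to 22.9 ± 1.52. Apol7c fell from 876 ± 38.4 to 10.9 ± 2.33 and the guanylate-binding protein gene Gbp10 from 209 ± 11.1 to 14.9 ± 4.20. The others were Adam11 (log2 fold change -6.58), Cnga1 (-5.71), Art2b (-4.74), Adam23 (-3.87) and Mab21l3, which fell from 110.2 ± 1.51 to 2.12 ± 2.25 normalized counts, to below the floor. Without MCDHFD replicate 2 the log2 fold change of Il12b went from -4.25 to -3.25. Gbp10 has similar family members, so its value is uncertain.

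Genes of CD8 T cell identity fell as a group: 19 of 19 were lower (median log2 fold change -0.997, camera adjusted p = 1.84e-10, adjusted p = 0.407 with an estimated correlation). Cd2 (log2 fold change -1.56), Cd3g (-1.49) and Themis (-1.47), which serve adhesion, receptor signalling and thymocyte selection, fell most. The summed share of the list in all normalized counts fell from 0.812% ± 0.00268 to 0.405% ± 0.0275 (SD, n = 3). Markers of other cells moved in the same libraries. Of 29 monocyte and macrophage genes, 25 rose and 3 fell (median log2 fold change 1.91, camera adjusted p = 7.53e-10, adjusted p = 0.407 with an estimated correlation), and their summed share rose from 0.561% ± 0.0507 to 2.68% ± 0.292. Vcam1, abundant in splenic red pulp macrophages, rose from 12596 ± 1164 to 56721 ± 5802, Hmox1, the haem-degrading enzyme, from 10278 ± 1326 to 63016 ± 8499, and Apoe, a lipid carrier, from 2710.3 ± 392 to 42408 ± 4889 normalized counts.

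Erythroid genes rose in 21 of 21 (median log2 fold change 3.38, camera adjusted p = 8.52e-11, adjusted p = 0.407 with an estimated correlation), with Hbb-bs going from 942 ± 12.6 to 5790.3 ± 1771, Hba-a1 from 449 ± 17.6 to 3244 ± 1051 and Tfrc, the transferrin receptor, from 1551 ± 31.9 to 2856 ± 63.5. The globin genes have near-identical copies, so their single values are uncertain. Of 20 neutrophil genes, 17 rose and 1 fell (median log2 fold change 3.50, camera adjusted p = 1.12e-06, adjusted p = 0.407 with an estimated correlation), among them Ngp (log2 fold change 4.12), S100a9 (2.88) and Chil3 (5.54). Plasma cell genes rose in 8 of 11 (median log2 fold change 1.35, camera adjusted p = 0.00182, adjusted p = 0.41 with an estimated correlation), with the immunoglobulin genes Ighg2b from 308 ± 20.4 to 5724 ± 1236 and Igha from 1330.4 ± 215 to 4218 ± 1096, and the secretory factor Xbp1 from 1482 ± 110.3 to 2327 ± 155. B cell genes fell in 14 of 17 and rose in 2 (median log2 fold change -1.88, camera adjusted p = 1.80e-05, adjusted p = 0.407 with an estimated correlation), where Ighd fell (log2 fold change -1.98) and Ighm (0.41) and Igkc (1.80) rose. The summed share of the B cell list went the other way from its median, from 0.183% ± 0.00909 to 0.203% ± 0.0193. Dendritic cell genes fell in 15 of 20 and rose in 2 (median log2 fold change -1.54, camera adjusted p = 2.54e-06, adjusted p = 0.262 with an estimated correlation), including the antigen presentation genes Cd74 (-1.48), H2-Ab1 (-1.50) and H2-Aa (-1.46). Gamma delta T cell genes fell in 4 of 5 (median log2 fold change -1.62, camera adjusted p = 0.0245, adjusted p = 0.41 with an estimated correlation), with Cd163l1 (-1.62), Blk (-1.67) and Trdc (-1.16). Of these 5 genes, 2 are also in another list, among them Blk, which is in the B cell list.

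**Figure D2:**
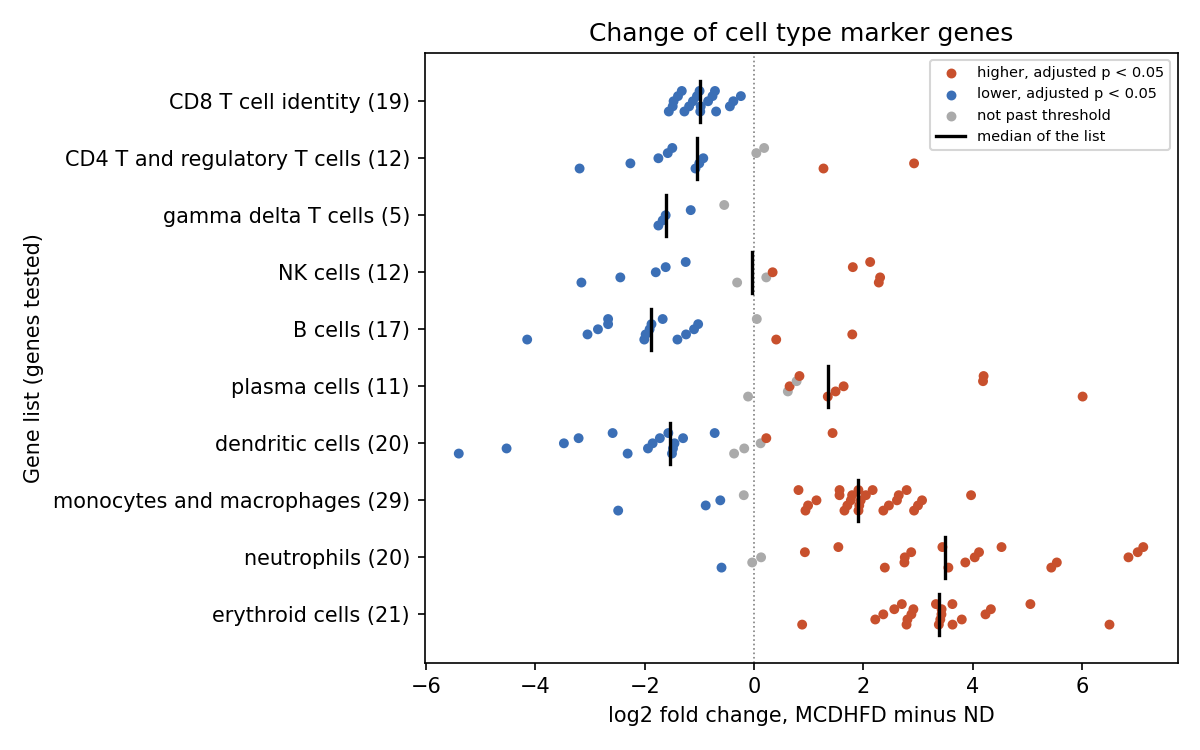
Log2 fold changes (MCDHFD minus ND, horizontal axis) of the tested genes of 10 cell type lists, 1 point per gene, with the list median as a black bar and points coloured by whether the gene was higher, lower or not past an adjusted p of 0.05. The erythroid and neutrophil medians lie at 3.38 and 3.50, and the CD8 identity and B cell medians at -0.997 and -1.88; with the identity genes held equal, the identity median lies near 0 by construction.

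Lists of NK cells (5 of 12 higher and 5 lower, camera adjusted p = 0.761), CD4 and regulatory T cells (2 of 12 higher and 8 lower, camera adjusted p = 0.111), megakaryocytes and platelets (4 of 9 higher and 2 lower, camera adjusted p = 0.554) and stroma and endothelium (3 of 8 higher and 1 lower, camera adjusted p = 0.404) did not pass as groups. The summed share of the CD4 and regulatory T cell list rose from 0.0388% ± 0.00241 to 0.0988% ± 0.0119, against its fall in most genes, and that of the NK cell list from 0.0396% ± 0.00314 to 0.0991% ± 0.00789. Of the NK cell list, the Fc receptor genes Fcgr3 (log2 fold change 2.31) and Fcer1g (2.28), also expressed by macrophages, rose, as did the T and NK cell kinase gene Txk (0.34). Of the CD4 list, Cd5l (2.93) rose, a secreted macrophage protein that is also in the macrophage list. The summed shares of these lists therefore do not follow CD4 T or NK cells alone. The platelet genes Clec1b (2.07) and Itgb3 (-2.31) went opposite ways, and the endothelial genes Pecam1 (0.40) and Stab2 (1.64) rose. Of the 3 tested mast cell and basophil genes, 2 rose and none fell, too few for a list test.

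T cell state genes fell more often than they rose, in libraries where the identity genes fell too. Naive and central memory genes fell in 13 of 18 and rose in 3 (median log2 fold change -0.46, camera adjusted p = 0.00193, adjusted p = 0.41 with an estimated correlation). Among them was the chemokine receptor gene Ccr9 (log2 fold change -3.48), which is also in the dendritic cell list. Dapl1 (-1.64) and Foxo1 (-0.96), a transcription factor of quiescence, fell as well. With the identity genes held equal, 13 of these 18 were higher and 2 lower, with a median of 0.53 against 0.99 for all tested genes. Cytotoxic effector genes fell in 19 of 29 and rose in 5 (median log2 fold change -0.93, camera adjusted p = 0.00355, adjusted p = 0.41 with an estimated correlation), with 20 lower when adjusted over the list alone, and 11 were higher and 8 lower with the identity genes held equal. S1pr5 (from 32.3 ± 2.78 to 2.31 ± 2.35 normalized counts, to below the floor), the chemokine gene Xcl1 (log2 fold change -2.58), interferon gamma Ifng (-2.13) and its regulator Tbx21 (-2.00) fell. Homing genes fell in 13 of 19 and rose in 2 (median log2 fold change -0.87, camera adjusted p = 0.00355, adjusted p = 0.407 with an estimated correlation), against 7 higher and 7 lower with the identity genes held equal. The chemokine receptor genes Cxcr6 (-2.96), Ccr6 (-2.55) and Cxcr3 (-1.82) fell and Rgs1 (1.90) rose. Activation genes fell in 12 of 20 and rose in 1 (median log2 fold change -0.69, camera adjusted p = 0.00958, adjusted p = 0.407 with an estimated correlation), against 10 higher and 6 lower with the identity genes held equal. Il2ra (-2.26) and Tnfrsf9 (-2.14) fell. The call of the activation list ended at a filter of a mean of 100 (median log2 fold change -0.23, camera adjusted p = 0.180).

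Exhaustion and inhibitory receptor genes did not pass as a group (4 of 20 higher and 10 lower, camera adjusted p = 0.093), with Cd101 (-2.49) and the transcription factor Eomes (-2.31) lower and Cd38 (2.17) and Cd244a (2.12) higher. The memory phenotype list did not pass either (5 of 16 higher and 9 lower, camera adjusted p = 0.404), with 6 higher when adjusted over the list alone, and with Samd3 lower (-1.67) and Fcgrt higher (1.45).

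Interferon response genes fell in 32 of 37 and rose in none (median log2 fold change -1.17, camera adjusted p = 6.19e-12, adjusted p = 0.354 with an estimated correlation). Ifi27l2a fell from 755 ± 85.7 to 89.7 ± 9.82 normalized counts, and Ifi44 (log2 fold change -2.91), Oasl2 (-2.50) and Usp18 (-2.39) fell as well. The dendritic cell list fell in the same libraries. With the identity genes held equal, 11 of these 37 were higher and 14 lower, with a median of -0.17 against 0.99 for all tested genes.

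Genes of lipid uptake and of fatty acid oxidation rose. Of 26 lipid uptake and storage genes, 21 rose and 2 fell (median log2 fold change 1.11, camera adjusted p = 3.50e-07, adjusted p = 0.407 with an estimated correlation), and 22 rose when adjusted over the list alone. The fatty acid carrier gene Fabp4 (log2 fold change 3.67), the lipoprotein receptor gene Lrp1 (3.20) and the lipid droplet gene Plin2 (2.88) rose, next to Apoe, which is also in the macrophage list. Fatty acid oxidation genes rose in 19 of 30 and fell in 2 (median log2 fold change 0.49, camera adjusted p = 0.00239, adjusted p = 0.407 with an estimated correlation), among them Crat (1.52), Acsl1 (1.32), Eci2 (1.07) and Cpt1a (1.04), which controls fatty acid entry into mitochondria. Cholesterol biosynthesis genes went the other way, with 15 of 24 lower and 1 higher (median log2 fold change -0.45, camera adjusted p = 0.00192, adjusted p = 0.407 with an estimated correlation), such as Nsdhl (-1.16) and Fdft1 (-0.90), and with the identity genes held equal 19 were higher and none lower, with a median of 0.54 against 0.99 for all tested genes. The macrophage share of counts rose in the same libraries as these lipid genes.

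Oxidative stress and glutathione genes rose in 26 of 31 and fell in 2 (median log2 fold change 0.86, camera adjusted p = 2.60e-07, adjusted p = 0.407 with an estimated correlation), with 27 higher when adjusted over the list alone. Beside Hmox1 and Mt2 these were Mt1 (log2 fold change 3.90) and the glutathione transferase gene Mgst1 (3.68). ATF4 amino acid response genes rose in 16 of 31 and fell in 7 (median log2 fold change 0.27, camera adjusted p = 0.0295, adjusted p = 0.41 with an estimated correlation), and 17 rose when adjusted over the list alone. Asparagine synthetase Asns (4.41), the glycine transporter gene Slc6a9 (2.97) and the mTOR inhibitor gene Ddit4 (2.79) rose. The ATF4 call ended without ND replicate 1 (median 0.28, camera adjusted p = 0.0573) and at a filter of a mean of 100 (median 0.19, camera adjusted p = 0.132). Macrophage and erythroid genes rose in the same libraries as these lists, and Hmox1 is also in the macrophage list.

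Other metabolic lists did not pass as groups: glycolysis (7 of 23 higher and 5 lower, camera adjusted p = 0.804), the TCA cycle (12 of 28 higher and 3 lower, camera adjusted p = 0.184), nuclear OXPHOS (10 of 70 higher and 7 lower, camera adjusted p = 0.801), mitochondrially encoded genes (4 of 13 higher and 1 lower, camera adjusted p = 0.404), mitochondrial biogenesis (8 of 24 higher and 5 lower, camera adjusted p = 0.773), fatty acid synthesis (7 of 14 higher and 4 lower, camera adjusted p = 0.554), methionine and one-carbon metabolism (9 of 32 higher and 6 lower, camera adjusted p = 0.696) and choline and phospholipid metabolism (14 of 26 higher and 5 lower, camera adjusted p = 0.111). Single members rose, such as the cytosolic isocitrate dehydrogenase gene Idh1 (log2 fold change 2.45), Aco1 (0.88), the desaturase gene Fads2 (3.42, and 2.79 without ND replicate 2 and 4.17 without ND replicate 3), the amino acid transporter gene Slc43a2 (1.81), Pld1 (1.93) and Pcyt1b (1.92), while Elovl7 (-1.90) fell. Cth rose from 0.66 ± 1.14 to 24.7 ± 8.84 normalized counts, from below the floor. Adjusted over the list alone, 8 nuclear OXPHOS genes were higher and 5 lower.

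Of the epigenetic lists, chromatin remodelling passed, with 17 of 36 lower and 4 higher (median log2 fold change -0.15, camera adjusted p = 0.0131, adjusted p = 0.41 with an estimated correlation). The helicase gene Chd3 fell from 16016 ± 1388 to 3972 ± 333 normalized counts (log2 fold change -2.01). With the identity genes held equal, 35 of these 36 were higher, with a median of 0.84 against 0.99 for all tested genes. The list of histone lysine methyltransferases also took in arginine methyltransferases, such as Prmt2. It did not pass as a group (5 of 36 higher and 16 lower, camera adjusted p = 0.181). Histone demethylases (4 of 23 higher and 8 lower, camera adjusted p = 0.486), DNA methylation genes (4 of 17 higher and 4 lower, camera adjusted p = 0.87), histone acetyltransferases (4 of 22 higher and 6 lower, camera adjusted p = 0.761) and histone deacetylases (3 of 23 higher and 12 lower, camera adjusted p = 0.111) did not pass either. The arginine methyltransferase gene Prmt2 fell (log2 fold change -1.67) and the lysine methyltransferase gene Smyd2 rose (1.21). The DNA methylation genes Uhrf2 (-0.67), Tet1 (-0.58) and Dnmt1 (-0.56) fell, and with the identity genes held equal all 3 were higher, by less than the shift of all tested genes.

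Profibrotic and repair factor genes rose in 12 of 16 and fell in 1 (median log2 fold change 0.97, camera adjusted p = 0.00373, adjusted p = 0.407 with an estimated correlation). The growth factor genes Hbegf (log2 fold change 3.10) and Tgfb2 (2.60), the matrix protease gene Mmp14 (2.86) and the galectin gene Lgals3 (1.73) rose, in the libraries where the macrophage share rose. TGF-beta signalling genes did not pass as a group (7 of 16 higher and 2 lower, camera adjusted p = 0.404), though Id1 (2.92) rose. Cell cycle genes rose in 22 of 44 and fell in 4 (median log2 fold change 0.37, camera adjusted p = 0.0187, adjusted p = 0.691 with an estimated correlation), with E2f8 (2.02) and Ccne2 (1.39), in libraries where erythroid genes rose too. The cell cycle call ended without MCDHFD replicate 3 (median 0.26, camera adjusted p = 0.0528). MYC and ribosome biogenesis genes rose in 15 of 30 and fell in 1 (median log2 fold change 0.14, camera adjusted p = 0.0114, adjusted p = 0.407 with an estimated correlation), with Eif5a (0.54) and Gnl3 (0.50).

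**Figure D3:**
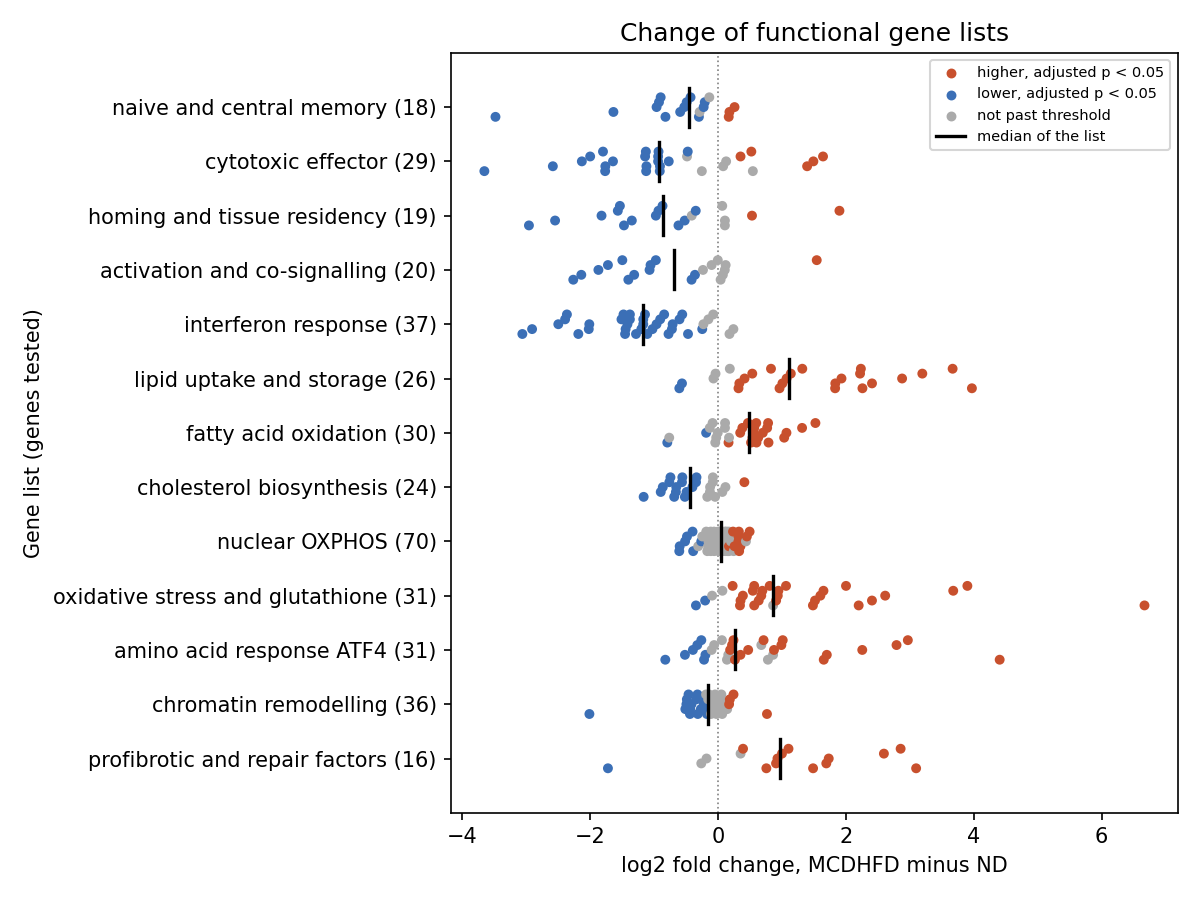
Log2 fold changes (MCDHFD minus ND, horizontal axis) of the tested genes of 13 functional lists, 1 point per gene, with the list median as a black bar and points coloured by the test result. The lipid uptake and oxidative stress medians lie at 1.11 and 0.86, and the interferon response median at -1.17. With the identity genes held equal, the cholesterol biosynthesis and chromatin remodelling medians were 0.54 and 0.84, against 0.99 for all tested genes.

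The remaining lists did not pass as groups: immediate early genes (11 of 25 higher and 8 lower, camera adjusted p = 0.565), NF-kB genes (7 of 20 higher and 11 lower, camera adjusted p = 0.289), apoptosis and p53 (6 of 24 higher and 3 lower, camera adjusted p = 0.569), the unfolded protein response (10 of 24 higher and 3 lower, camera adjusted p = 0.161), hypoxia (9 of 19 higher and 3 lower, camera adjusted p = 0.217) and ribosomal proteins (7 of 85 higher and 21 lower, camera adjusted p = 0.14). Egr3 (log2 fold change -2.62) and Traf1 (-1.71) fell, and the chaperone gene Hspa1a (2.62) and the inflammasome gene Nlrp3 (1.92) rose. Of the lists that could show a change of library type, those of replication-dependent histones and of nuclear long noncoding RNAs did not pass. The histone list (2 of 24 higher and 6 lower, median log2 fold change -0.59, camera adjusted p = 0.15) also took in the replacement histone gene H1f0. The noncoding list had 1 of 7 higher and 2 lower (camera adjusted p = 0.877). Small structured RNAs (2 of 2 higher) and Y-linked genes (1 of 4 higher and 1 lower) had too few tested members. Xist, listed with the Y-linked genes, lay below the filter, at 15.5 ± 18.4 normalized counts in ND and 3.74 ± 0.841 in MCDHFD. ND replicate 3 held 36.6.

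In total 22 of the 50 tested lists passed camera at its preset correlation, 11 higher and 11 lower, and none of these calls held with a correlation estimated from the 6 libraries. With the identity genes held equal, the medians of all 22 lay on the same side of the median of all tested genes as before, and none moved by more than 0.0474 relative to it. As that scaling adds about the same amount to every gene, it does not test the calls. The gamma delta call ended with no filter (median -0.91, camera adjusted p = 0.0545), the cell cycle call with fry (adjusted p = 0.0607), and the ATF4 call without genes of other cell lists (median 0.25, camera adjusted p = 0.056). Where no other count is given, the counts of higher and lower genes were the same when adjusted over the list alone, with these exceptions. There were then 16 dendritic cell genes lower, 6 ribosomal protein genes higher and 15 lower, 2 stroma and endothelium genes higher, and 3 replication-dependent histone genes lower.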

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

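The CD8 identity scaling, the omission of other cell genes and the lists without such genes were chosen after seeing the data. The count of 7837 genes stayed within 1.5 times under the other pseudocounts, filters, TMM, quantile and weighted fits, from 6086 at a filter of a mean of 100 to 8247 with no filter. edgeR on the recovered reads of 5 libraries called 7136 genes and DESeq2 6715. Without 1 library each the count ran from 7069 to 7677, with 3644 to 3965 higher and 3308 to 3712 lower, and the lists from 21 to 23. At least 2-fold changes numbered 2785 (1756 higher, 1029 lower), since the fold limit removes smaller changes. With genes of other cell lists left out, 7575 genes passed. The CD8 identity scaling gave 11056 higher and 488 lower, since it raises every MCDHFD value, and 2088 calls reversed.

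Trnp1 kept its direction and its side of the threshold under every alternative run, and without 1 library each its log2 fold change ran from 3.61 to 3.82. The lists that passed numbered 0 with an estimated correlation, of 22, and 37 with the self-contained test fry, which asks another question. Under the identity scaling the list of chromatin remodelling turned to a median of 0.84, below the 0.99 of all tested genes, and Foxo1 to 0.034, Fdft1 to 0.093, Uhrf2 to 0.32, Tet1 to 0.41 and Dnmt1 to 0.44, because that scaling adds about the same amount to every gene. No other gene in the text changed sign, but Cd3e (from -0.997 to -0.003, SE 0.07 and 0.06), Nsdhl (from -1.16 to -0.17, SE 0.13 and 0.15) and Trdc (from -1.16 to -0.17, SE 0.23 and 0.22) lost their calls, as it raised them by that amount, and Cd4 passed. Foxo1 (limma adjusted p = 0.618) and Fdft1 (limma adjusted p = 0.543) also lost their calls, so only their sign turned. Under that scaling 25 lists passed: 15 as before, chromatin remodelling in the other direction (camera adjusted p = 0.0489), and 9 that had not. The latter were exhaustion, memory phenotype, CD4 T cell, NK cell and replication-dependent histone genes with camera's direction down, and TCA cycle, unfolded protein response, ribosomal protein and histone acetyltransferase genes with it up, though the medians of the last 2 lay below that of all tested genes. The other 6 no longer passed: naive and central memory (camera adjusted p = 0.155), cell cycle (camera adjusted p = 0.194), cholesterol biosynthesis (camera adjusted p = 0.299), ATF4 (camera adjusted p = 0.0661), profibrotic (camera adjusted p = 0.316) and plasma cell genes (camera adjusted p = 0.194). Their medians relative to all tested genes moved by no more than 0.0474. Of all 212 genes that the naming rule takes, 33 reversed under that scaling and 0 under any other alternative, while 13 lost their call under at least 1 other alternative. Only 5 of these 33 and 0 of these 13 are in the text, as examples were narrowed after stability was seen, so counts over genes in the text understate how often calls changed. With the replicate number as a block, 7707 genes passed, against 7837 without the block. The deviations of same-numbered libraries correlated at 0.036, 0.062 and 0.0057, too low to pair them, and ND replicate 3 correlated more with MCDHFD replicate 1 (0.020) than with its own number. Depth limits the genes near the filter, whose counts are few.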

Other observations

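The tests of the splits, of scaling, of macrophages, of cell proportions, of the identity genes' spread and against Cd2 were chosen after the result was seen, as were the pancreatic genes and the choice of Eomes, Cxcr3 and Cxcr6. The bounds of the erythroid and natural killer tests were set before the compared values were seen. Of 23 pancreatic transcripts looked at, 18 were higher in each MCDHFD library than in each ND library, and 15 of these had a mean below a floor of 3 counts per library in ND only. Cpa1 was at 0 in the ND libraries and at 65.1 ± 15.8 normalized counts (mean ± SD, n = 3) in MCDHFD. Try4 (53.4 ± 21.9), Cela3b (49.3 ± 21.9), Pnliprp1 (38.1 ± 17.0) and Cpb1 (34.5 ± 6.51) showed the same 0 in ND. The elastase gene Cela1 went from 102 ± 16.3 to 814 ± 102. The other 5 did not follow. Ctrl, at 11.4 ± 3.92 in ND and 19.5 ± 8.62 in MCDHFD, and Pnlip, at 0.653 ± 1.13 and 3.54 ± 3.48, overlapped between the diets. Ctrc (1.31 ± 1.49 in ND, 0 in MCDHFD), Clps (0 in ND, 2.85 ± 3.38 in MCDHFD) and Try10 (0 in ND, 0.627 ± 1.09 in MCDHFD) had means below the floor in both. Alb, the main liver secretory transcript, was at 0 in ND and at 0.627 ± 1.09 in MCDHFD, below the floor.

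Over the 10 splits of the 6 libraries into 3 and 3, the real one gave 7837 genes and the highest other split gave 0, so 1 split gave as many. With 10 splits, no share under 0.05 can be reached.

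Trnp1 was higher in MCDHFD by a log2 fold change of 3.73. Under TMM, quantile and CD8 identity scaling its lowest value was 3.66. These scalings moved the median log2 fold change of all tested genes from 0.004 to -0.004, -0.083 and 0.99. None of these moves could undo 3.73, so they cannot decide on the scaling of the libraries as the source. A larger share of unchanged macrophages stays open, since Trnp1 lay 1.36 SDs above the macrophage median, with 28 of 29 macrophage genes changing less. A larger share of erythroid cells also stays open: the rise of Trnp1, 2163 normalized counts, was 0.784 of the median rise of Hbb-bs, Hba-a1, Slc4a1, Car2 and Car1, as an erythroid transcript could show. Other cell types whose genes rose were not tested as sources and stay open too. Among them were neutrophils (median log2 fold change 3.50, 17 of 20 higher and 1 lower) and plasma cells (median 1.35). A change within CD8 T cells, the difference the design names, was not tested, because bulk libraries do not assign a transcript to a cell type.

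The CD8 T cell identity genes were lower in 19 of 19. The macrophage and B cell medians differed by 3.79 on the log2 scale, more than the sum of their SDs of 2.75. By summed share, though, the B cell list rose from 0.183% to 0.203%. This pair was chosen after its opposite medians were seen, and changed expression per cell could also part them. It therefore cannot decide on fewer T cells with the other types in unchanged proportions. TMM and quantile scaling left 19 of 19 lower. They moved the median log2 fold change of all tested genes only from 0.004 to -0.004 and -0.083. That is too little to undo a list median of -0.997, so they cannot decide on the scaling of the libraries as the source. With the identity genes held equal, 7 of 19 were higher and 7 lower. A smaller share of T cells as part of the change stays open: their interquartile range was 0.562 of the median fall, and its bootstrap interval over genes (95%, 0.259 to 0.913) spans the bound of 0.5. Lower expression per T cell under MCDHFD may add to it and cannot be told apart from a smaller share in these data.

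Eomes, Cxcr3 and Cxcr6 were chosen because they fell by more than the identity genes, of which the lowest log2 fold change was -1.56. That fall was thus fixed by the choice, and only its size is described. With the identity list held equal, 3 of 3 were still lower (Eomes -1.32, SE 0.10, Cxcr3 -0.83, SE 0.13, Cxcr6 -1.97, SE 0.15). As the choice fixed this direction, it cannot decide on a smaller share of T cells as the whole cause. The identity genes themselves did not fall alike, with 7 of 19 higher and 7 lower under that scaling. Against Cd2, the lowest identity gene, 3 of 3 were lower by more than 2 SEs (Eomes -0.75, SE 0.07, Cxcr6 -1.40, SE 0.13, Cxcr3 -0.26, SE 0.11), Cxcr3 by 2.32. That they lay below Cd2 also follows from the choice, so this shows only the size of the gap. A smaller share of T cells as all or part of the fall stays open. Fewer natural killer cells, which also express Eomes, stay open as well. Of the 12 tested genes of the NK cell list, 5 fell, all by at least 2-fold, and 5 rose, 4 of them by at least 2-fold. The genes that rose include Fcgr3 and Fcer1g, which macrophages also express. The 10 receptor genes of natural killer cells summed to 222 ± 65.3 normalized counts in ND. That is within 2 SDs, a margin chosen after the result was seen, of the bound of 0.5 of the fall of Eomes (316 of 632). That bound, set before the result was seen, was wrong in assuming a ratio of receptors to Eomes that bulk libraries do not give. A change within CD8 T cells under MCDHFD was not tested.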
